A study of Rattus norvegicus with 46 samples.

How the data were processed

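RNA was measured in 46 brain samples of male Wistar rats, per the labels. Intact brain tissue or ischemic lesion tissue was taken, the latter 14 days after middle cerebral artery occlusion (MCAO), a model of ischemic stroke. The rats were 3 months old at the start. They ate either a standard diet, with 11% of its 3227 kcal/kg from fat, 24% from protein and 65% from carbohydrate, or a ketogenic diet, with 84%, 11% and 5% of its 6431 kcal/kg. The diets ran for 2 months before MCAO and for 2 more weeks after it. The groups were intact brain on the standard diet (8 libraries), intact brain on the ketogenic diet (8), lesion on the standard diet (11) and lesion on the ketogenic diet (19). Library names below are the group and the sample number in the labels.

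Per the labels' protocols, RNA was extracted with a column kit and polyA RNA libraries were made with a directional Illumina kit. The submitters' processing notes list bcl2fastq 2.20, FastQC 0.11.8, MultiQC 1.15, HISAT2 2.0.5, Cufflinks, HTSeq 0.7.2, DESeq2 1.42.0 and the build mRatBN7.2. The annotation release and the strand setting of the counting were not given in the sources used here, so overlapping and antisense genes were not told apart. The files the authors deposited hold raw counts per gene, with no normalization, for 30452 Ensembl gene IDs. The series-wide table held the same counts, with 0 cells differing from the per-sample files. It also held 39 columns of per-sample values that belong to no sample described here, and those were not used in any step.

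The files do not pair the gene IDs with names, and 0 of the 30452 IDs matched the gene table at hand, which is of another assembly (GRCr8). Genes are therefore given by ID. The 36 gene lists, with 601 genes, that were fixed before the data were examined were not tested, nor was the planned covariate for tissue composition. The rule for naming genes was fixed at the same time: called genes with a mean CPM of at least 1 and the largest changes, and, where no interaction passed, the 3 genes with the smallest p. Without names it was narrowed to at most 2 IDs that rose and 2 that fell per comparison.

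Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr for low counts and the robust quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Both MCAO contrasts and both diet contrasts were fitted on their own pair of groups, and the interaction of diet and MCAO on all 46 libraries. These 5 designs, the choice of alternatives and the naming rule were set before the data were examined. The alternatives set at that point were DESeq2 1.42.0, RLE scaling, no low-count filter, a minimum mean of 1 CPM and 2 surrogate variables from sva 3.50.0. They also held limma 3.58.1 voom with quality weights and, for the interaction, voom with weights by group. Further ones were 1 fit over all libraries, leaving out each library in turn, and drawing 11 of the ketogenic lesion libraries 20 times. Added after seeing the data were scaling by library totals only, thinning all libraries to the smallest total, an axis position or the share of the 20 most abundant genes as covariate, a fit of diet with tissue as an additive term, and log2 CPM with a prior count of 2 for the lesion readings.

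The axis position is the projection of a library's log2 CPM (prior count 2) on the difference between the mean lesion and the mean intact profile, scaled so that 0 is the mean of intact brain and 1 the mean of lesions. It was defined after the data were seen. The spread of a library is the mean squared distance in log2 CPM to the mean of the other libraries of its group. It was taken over the 500 genes with the largest variance across all 46 libraries. Differences in one value per library were tested with two-sided permutation tests, exact where a group had 8 libraries and with 100000 resamples otherwise. No pair of libraries in a group was alike within sampling noise: the smallest chi-square per degree of freedom was 12.8.

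The main edgeR fit of both MCAO contrasts and both diet contrasts was tested on simulated data with 200 changed genes. At a fold of 2, the fits recovered 89% of changed genes for MCAO on the standard diet, 77% for MCAO on the ketogenic diet, 87% for diet in intact brain and 84% for diet in lesions. The interaction, the alternatives and the fits added after seeing the data were not simulated. At a fold of 1.41 the shares were 43%, 30%, 49% and 39%. False calls made up 3.65%, 10.1%, 4.90% and 3.15% of calls, in the same order. Few genes changed in the simulation, evenly up and down, and counts were drawn independently for each gene. The real MCAO contrasts called 68.4% and 69.1% of genes, and lesion libraries varied along a common axis. The simulated shares therefore do not describe recovery or false calls in the real MCAO and lesion diet fits. Random splits of the intact libraries gave up to 473 calls, which points to genes that vary together there too. The shares for diet in intact brain therefore do not describe its real fit either.

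Nothing in the labels says that each sample came from a separate rat, so p-values measure the spread between these samples. No sequencing batch is labelled. All ketogenic samples have numbers from 3 to 59 and all standard-diet samples from 61 to 90, so a batch that follows the numbers and the diet cannot be told apart. Within each diet all lesion samples also have lower numbers than all intact samples. Such a batch therefore cannot be told apart from MCAO either, in any contrast of lesion and intact libraries. Intervals and floors based on counts cover counting error only. The floor for a gene without counts is 3 counts over the group.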

Results

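Transcript counts were obtained from intact brain and from ischemic lesions of rats on a standard or a ketogenic diet, to ask how the diet affects the brain and its state 2 weeks after an occlusion of the middle cerebral artery (MCAO). Library totals ranged from 8883068 to 18868791 counts in intact brain on the standard diet (n = 8) and from 12911844 to 20420918 in intact brain on the ketogenic diet (n = 8). They ranged from 17068206 to 22664327 in lesions on the standard diet (n = 11) and from 15290782 to 30601841 in lesions on the ketogenic diet (n = 19). Lesion libraries were deeper than intact ones on the standard diet (19130900 against 15635231 counts on average, exact permutation p = 0.00212, adjusted p = 0.00848 over 4 comparisons) and on the ketogenic diet (20782335 against 16078912, exact permutation p = 0.00459, adjusted p = 0.00918). Totals did not differ detectably between diets, in intact brain (exact permutation p = 0.775) or in lesions (permutation p = 0.201).

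A few abundant genes weighed more in intact brain. The 20 most abundant genes of each library held 24.5% ± 4.5 (SD, n = 8) of counts in intact brain on the standard diet and 18.5% ± 3.4 (SD, n = 8) on the ketogenic diet (exact permutation p = 0.0107, adjusted p = 0.0143 over 4 comparisons). In lesions the shares were 12.7% ± 0.80 (SD, n = 11) and 12.5% ± 1.0 (SD, n = 19), with no detectable difference between diets (permutation p = 0.568, adjusted p = 0.568). Both lesion groups lay below the intact group of their diet, with exact permutation p of 1.32e-05 and 1.35e-06. Intact and lesion libraries separated on the first principal component, which held 76.5% of the variance of the 2000 most variable genes.

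**Figure D1:**
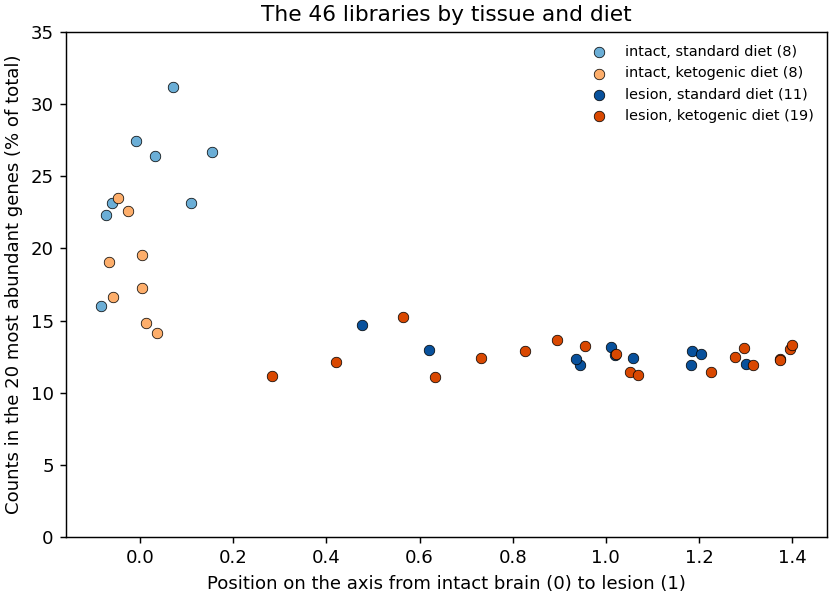
Each point is 1 of the 46 libraries. The horizontal axis is its position between the mean intact profile (0) and the mean lesion profile (1), and the vertical axis the percent of its counts in its 20 most abundant genes. Lesion libraries spread from 0.28 to 1.40, while intact libraries stay between -0.08 and 0.15.

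The first comparison asked which genes differed between the ischemic lesion and intact brain on the standard diet. Of 15446 genes tested, 5291 were higher and 5272 lower in lesions (edgeR, 11 against 8 libraries), which is 68.4% of genes. The largest changes were rises. By fitted fold change, 2360 genes rose and 833 fell at least 2-fold, 1065 rose and 34 fell at least 4-fold, and 167 rose and 0 fell at least 16-fold. The median size of a called change was 0.70 on the log2 scale. With genes of 3 or fewer intact counts set to their floor, the 16-fold count stayed at 167 and the median at 0.70.

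The strongest rises started from few or no intact counts. By mean lesion level, 15 genes went from at most 3 counts over the intact group to at least 1 CPM, but 0 genes did so in every lesion library, on this or the ketogenic diet. In the other direction, 9 genes went from a mean of at least 1 CPM in intact brain to at most 3 counts over the lesions. All 9 were highest in standard-diet intact library 83, 0 of them reached a mean of 1 CPM over the 7 others of its group, and 0 passed the filter for testing. ENSRNOG00000029949 had 0 counts in the 8 intact libraries and 2.30 ± 1.92 CPM (SD, n = 11) in lesions, which is at least 80.2-fold higher against a floor of 3 counts over the intact group (adjusted p = 6.79e-06). ENSRNOG00000019043 had 1 count in intact brain and 5.22 ± 3.42 CPM (SD, n = 11) in lesions, a pooled ratio of 560 with a counting interval from 100.3 to 22132 (adjusted p = 5.30e-08). For both IDs, 11 of 11 lesion libraries lay above the highest intact library. The largest falls were smaller. ENSRNOG00000063919 went from 12.04 ± 4.72 CPM (SD, n = 8) to 1.47 ± 0.49 CPM (SD, n = 11), a log2 fold change of -3.05 (SE 0.23, adjusted p = 4.68e-09). ENSRNOG00000063840 went from 7.59 ± 3.995 to 1.11 ± 0.42 CPM, a log2 fold change of -2.78 (SE 0.30, adjusted p = 1.39e-07). For these IDs 0 of 11 lesion libraries lay above the highest intact one.

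The even balance of rises and falls depends on the scaling of libraries. With library totals only, an alternative chosen after seeing the data, 76.6% of calls were higher in lesions against 50.1% with TMM, and the median gene shifted by 0.34 on the log2 scale. Group ranges did not overlap for 1804 higher and 1577 lower genes of the 14619 with a mean of at least 1 CPM, where chance gives 0.00265% of genes.

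The same contrast on the ketogenic diet gave a response of similar extent. Of 15862 genes tested, 5589 were higher and 5379 lower in lesions (edgeR, 19 against 8 libraries), or 69.1% of genes. At least 2-fold changes were 2771 rises and 1076 falls, at least 4-fold changes 1357 rises and 39 falls, and at least 16-fold changes 254 rises and 0 falls (252 rises with low intact counts at their floor). The median size of a called change was 0.77 on the log2 scale, and it was 0.77 with those genes at their floor.

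The largest rises varied widely between lesions. ENSRNOG00000030187 had 0 counts in intact brain and 15.4 ± 24.7 CPM (SD, n = 19) in lesions, between 0 and 70.9 CPM, which is at least 603-fold higher against the floor over the group (adjusted p = 0.00175). ENSRNOG00000010507 had 0 counts in intact brain and 5.81 ± 9.08 CPM (SD, n = 19) in lesions, at least 223-fold higher (adjusted p = 0.00280). These bounds rest on pooled counts, with an SD between lesions above the mean, and the fitted size fell with another method: the log2 fold changes were 11.25 and 9.84 with edgeR, and 5.48 and 4.17 with limma voom and quality weights, where both calls held. For each of them 18 of 19 lesion libraries lay above all intact libraries. ENSRNOG00000036831 went from 8.21 ± 5.21 CPM (SD, n = 8) to 0.76 ± 0.26 CPM (SD, n = 19), a log2 fold change of -3.45 (SE 0.24, adjusted p = 7.88e-12). ENSRNOG00000063840 fell on this diet as well, from 8.95 ± 4.36 to 0.91 ± 0.35 CPM, with a log2 fold change of -3.31 (SE 0.22, adjusted p = 3.91e-12). With library totals only, 69.1% of calls were higher against 51.0%, and the median gene shifted by 0.25. Group ranges did not overlap for 1178 higher and 1004 lower genes of 14645, where chance gives 9.01e-05%.

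The lesion response was alike on both diets gene by gene. Across the 15433 genes tested in both comparisons, which share no libraries, the log2 fold changes had a Pearson r of 0.970 and a Spearman rho of 0.960, and the slope of the ketogenic on the standard-diet change was 1.06. These correlations are across genes, which are not independent replicates. Called in both were 4785 higher genes, where independent lists of these sizes would share 1847, and 4585 lower genes, where they would share 1813. Only 1 gene was called in opposite directions. Genes called on one diet alone were 1187 for the standard and 1329 for the ketogenic diet, and of all standard-diet calls 99.5% had the same sign on the ketogenic diet.

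**Figure D2:**
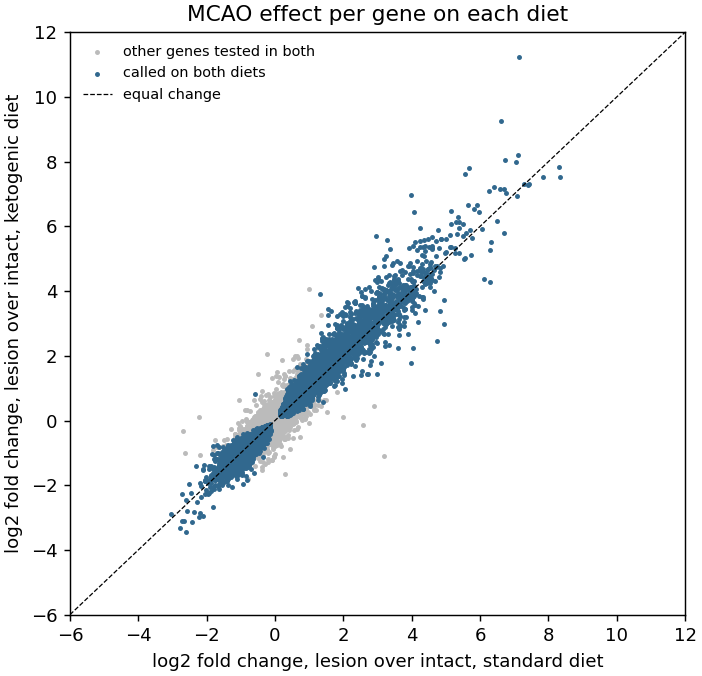
Each point is 1 of the 15433 genes tested in both comparisons, with its log2 fold change of lesion over intact brain on the standard diet (horizontal) and on the ketogenic diet (vertical). Genes called on both diets are in blue, other genes in grey, and the dashed line marks equal change; the slope was 1.06.

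Whether MCAO acts differently on the diets was tested directly as an interaction over all 46 libraries. With edgeR 0 of 16140 genes passed, with 719 at an unadjusted p under 0.05 where 807 are expected by chance. DESeq2 called 2 genes, limma voom with quality weights 13 and edgeR with 2 surrogate variables 10. The smallest adjusted p of edgeR was 0.152, for ENSRNOG00000067865 (log2 interaction 1.47, SE 0.29), which did not pass; over the alternatives its adjusted p ran from 0.0147 to 0.714. Its mean went from 1.12 to 1.17 CPM with MCAO on the standard diet and from 0.54 to 1.56 CPM on the ketogenic diet. ENSRNOG00000017884 (log2 interaction -0.77, SE 0.18) and ENSRNOG00000027145 (16.4 to 9.41 CPM with MCAO on the standard and 10.99 to 13.99 CPM on the ketogenic diet) had the next smallest p, each with an adjusted p of 0.555, and did not pass. Over the alternatives their adjusted p ran from 0.0236 to 0.714, with ENSRNOG00000017884 past the threshold with limma voom and quality weights and with 2 surrogate variables, and from 0.0615 to 0.714. Library 83 raised the intact standard-diet mean of ENSRNOG00000027145, at 35.4 CPM against 16.1 in the next. Of 9371 genes called on both diets, 7504 (80.1%) had a 95% interval of the interaction within 2-fold. The remaining intervals were wider, so larger differences for those genes were not excluded. Over all 16140 genes tested, 48.7% had an interval within 1.5-fold. A 2-fold difference exceeds the median called MCAO change, which was 0.70 on the standard and 0.77 on the ketogenic diet (log2 scale). Intervals within 2-fold therefore do not show equal responses.

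In intact brain, the diet comparison asked which genes the ketogenic diet moves without ischemia. With edgeR 0 of 14746 genes were called (8 against 8 libraries, smallest adjusted p = 0.0803), with 2181 genes at an unadjusted p under 0.05, 1197 higher and 984 lower, where 737 are expected by chance. DESeq2 called 275 genes, 157 higher and 118 lower on the ketogenic diet. The 95% interval of the fold change lay within 2-fold for 94.6% of genes and within 1.5-fold for 75.6%. The edgeR count rose to 170 without ketogenic library 59, to 9 without standard-diet library 85, to 2 without standard-diet library 90 and to 1 without ketogenic library 47. The intact libraries of the diets also differed in the share of their 20 most abundant genes, given above; with that share as a covariate, added after seeing the data, 704 genes had an unadjusted p under 0.05, of which 457 were among the 2181.

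In lesions, 117 of 15782 genes differed between diets (edgeR, 19 against 11 libraries), 73 higher and 44 lower on the ketogenic diet. The changes were small: 0 genes reached 2-fold, the median size was 0.29 and the largest 0.72 on the log2 scale. ENSRNOG00000069594 was 4.14 ± 1.22 CPM (SD, n = 19) on the ketogenic and 2.66 ± 0.67 CPM (SD, n = 11) on the standard diet, a log2 fold change of 0.65 (SE 0.16, adjusted p = 0.0474). ENSRNOG00000015333 was 1.19 ± 0.30 against 0.80 ± 0.19 CPM (log2 fold change 0.57, SE 0.14, adjusted p = 0.0464). Lower on the ketogenic diet were ENSRNOG00000070234, at 5.90 ± 1.11 against 8.67 ± 2.66 CPM (log2 fold change -0.55, SE 0.13, adjusted p = 0.0385), and ENSRNOG00000053406, at 1.58 ± 0.40 against 2.25 ± 0.34 CPM (-0.51, SE 0.13, adjusted p = 0.0474). Each of these 4 calls ended under some alternatives: over all of them the adjusted p ran from 0.00514 to 0.116 for ENSRNOG00000069594, from 0.00464 to 0.364 for ENSRNOG00000015333, from 0.00476 to 0.0575 for ENSRNOG00000070234 and from 0.00505 to 0.0816 for ENSRNOG00000053406.

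The number of diet calls in lesions rested on single libraries and on the fit. It was 6 without standard-diet library 70 and 242 without ketogenic library 37, and 20 of the 30 libraries moved it by over 1.5 times. Other fits gave from 21 genes, without a low-count filter, to 2324, with 2 surrogate variables. Of calls with TMM 62.4% were higher on the ketogenic diet, with RLE scaling 75.2% and with library totals only 33.3%.

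Lesions differed from one another in how far they lay from intact brain. On the axis position, lesions averaged 0.99 ± 0.25 (SD, n = 11) on the standard diet, from 0.48 to 1.30, and 1.01 ± 0.35 (SD, n = 19) on the ketogenic diet, from 0.28 to 1.40, with no detectable difference in mean (permutation p = 0.922, adjusted p = 0.922 over 2 comparisons). With the position as a covariate, added after seeing the data, 1715 genes differed between diets in lesions, 834 higher and 881 lower on the ketogenic diet, and the 117 were all among them. Intact libraries stayed near 0, at 0.02 ± 0.09 (SD, n = 8) on the standard and -0.02 ± 0.04 (SD, n = 8) on the ketogenic diet. The spread over the 500 most variable genes was 2.46 ± 1.76 (SD, n = 19) in ketogenic lesions and 0.65 ± 0.27 (SD, n = 8) in intact brain on that diet (exact permutation p = 0.0074, adjusted p = 0.0222 over 3 comparisons). Over all genes past the filter this difference did not pass (0.359 against 0.183, exact permutation p = 0.0248, adjusted p = 0.0744). Over the 500 genes the spread was 1.64 ± 1.29 (SD, n = 11) in standard-diet lesions and 0.78 ± 0.22 (SD, n = 8) in their intact group (exact permutation p = 0.0498, adjusted p = 0.0747, which did not pass). Over all genes it was 0.245 against 0.214 (exact permutation p = 0.598, adjusted p = 0.598). The 500 genes were picked by variance over all 46 libraries, so they favour genes that vary between lesions. The spread over them is therefore not an even test of lesions against intact brain. Over these genes the lesion groups did not differ detectably in spread (permutation p = 0.193, adjusted p = 0.193).

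Lesions with larger changes in the genes that rose with MCAO also had larger changes in those that fell. For each lesion library the size of its change was read on the CPM scale, as a fraction of the mean lesion change. It was read from 2092 genes called at least 2-fold higher and from 606 called at least 2-fold lower on both diets. Only genes with a mean of at least 1 CPM over all 46 libraries were taken. The medians ran from 0.077 to 1.71 for higher genes and from 0.59 to 1.30 for lower genes. The readings went together across the 30 lesions (Pearson r = 0.981, Spearman rho = 0.988, each with a permutation p of 1e-05, the smallest that 100000 resamples can give; r = 0.978 without the 2 farthest libraries). Within diets r was 0.975 (n = 11) and 0.982 (n = 19). Both gene sets were picked in these same libraries, so any single factor along the axis gives a high r. The correlations and their p therefore describe these libraries and are not a separate test. The slope of the lower-gene on the higher-gene reading was 0.404, with a 95% bootstrap interval from 0.368 to 0.436. On this scale a fall is limited by the intact level and a rise is not. On the log2 scale, added after seeing the data, the readings ran from 0.232 to 1.39 for higher genes (SD 0.318, n = 30) and from 0.430 to 1.56 for lower genes (SD 0.320, n = 30). Their slope there was 0.962, with a 95% bootstrap interval from 0.857 to 1.13, so no difference in variability between rising and falling genes was detected.

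**Figure D3:**
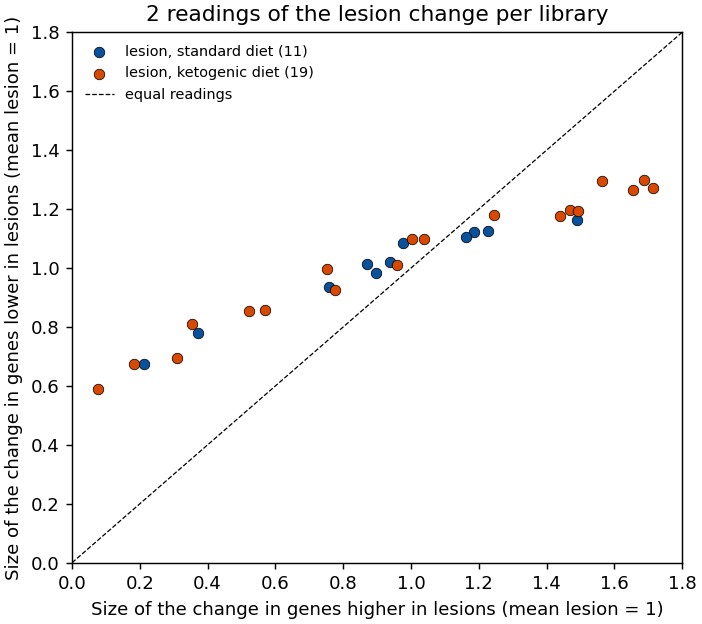
Each point is 1 of the 30 lesion libraries. The horizontal axis is the median size of its change over the 2092 genes higher in lesions and the vertical axis over the 606 genes lower in lesions, each on the CPM scale as a fraction of the mean lesion; the dashed line marks equal readings, and the points follow a slope of 0.404.

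Most genes called for diet in lesions had the same sign in intact brain. Of the 117 genes called in lesions, 115 were tested in intact brain, and 110 of these (95.7%) had the same sign. The named ENSRNOG00000069594 was an exception, at 2.32 ± 0.65 CPM (SD, n = 8) on the ketogenic and 3.01 ± 1.07 CPM (SD, n = 8) on the standard diet in intact brain. This difference did not pass there, and library 83 raised the standard-diet mean, at 5.33 CPM against 3.37 in the next. The median change of the 115 in their lesion direction was 0.19 in intact brain on the log2 scale. Across the 14661 genes tested in both, Pearson's r was 0.269 and Spearman's rho 0.355, across genes and not across replicates. These correlations were not beyond chance: of 100 splits of the intact libraries, the real one included, 8 had an r and 6 a rho as large in either direction, and the others ran from -0.372 to 0.319 for r and from -0.464 to 0.389 for rho. In one fit over both tissues, with diet and tissue as additive terms and added after seeing the data, 765 of 16140 genes differed between diets, 453 higher and 312 lower on the ketogenic diet, with a median size of 0.23 on the log2 scale. All ketogenic samples have lower sample numbers than all standard-diet samples, so the diet and any cohort that follows the numbers cannot be told apart.

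**Figure D4:**
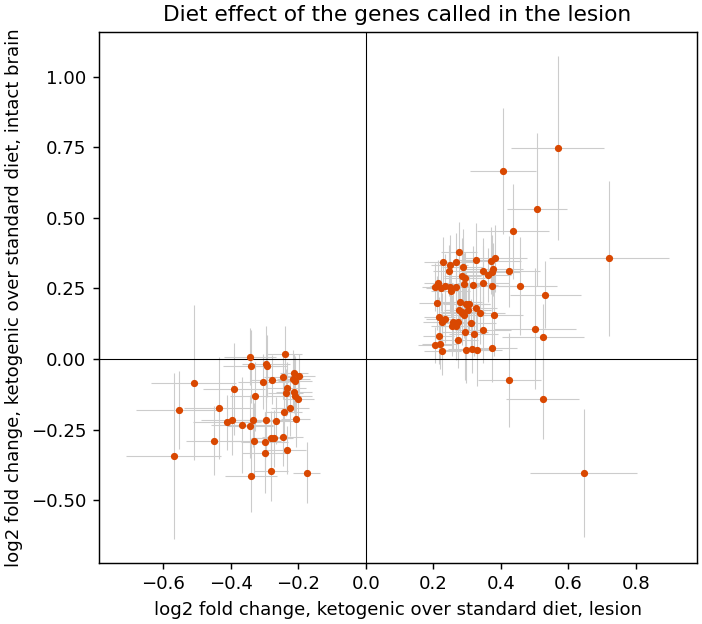
Each point is 1 of the 115 genes called for diet in lesions and tested in intact brain, with its log2 fold change of ketogenic over standard diet in lesions (horizontal) and in intact brain (vertical); bars are standard errors. In 110 of them both changes have the same sign.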

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

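In 39 sets of 8 intact libraries, 9 had a library at one end with a gap to the others beyond Dixon's 95% limit, where chance gives about 1.95 for normally distributed values. Most sets are CPM of IDs named from these same libraries, some with almost no counts, so the excess over 1.95 is not a test. Standard-diet intact library 85, the shallowest at 8883068 counts, had 16827 detected genes, against 17833 in the next lowest of its group. Ketogenic intact library 49 had a spread of 1.24 over the 500 most variable genes, against 0.785 in the next. For IDs near 0 in intact brain, 1 or 2 counts set the value: ENSRNOG00000029949 was at 0.0635 CPM in ketogenic library 47. ENSRNOG00000019043 was at 0.0614 CPM in standard-diet library 90 and at 0.104 CPM in ketogenic library 53, and ENSRNOG00000010507 at 0.123 CPM in standard-diet library 90. ENSRNOG00000036831 stood at 19.8 CPM in ketogenic library 51 against 11.5 in the next. In standard-diet intact library 83, ENSRNOG00000069594 stood at 5.33 CPM against 3.37 in the next, and ENSRNOG00000027145 at 35.4 CPM against 16.1.

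The weighing below covers 3 patterns. Chosen only after their results were seen were the tests of other splits, of axis position, of cohort, of depth for the lesion positions and for intact brain, of the equality of the lesion readings, and of the share of abundant genes as covariate with its overlaps. The tests of depth for the lesion diet genes, of the correlation of the lesion readings and of the slope on abundant genes were set down before their values were seen.

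The first pattern is the small diet difference in lesions, 117 genes, with the same sign in intact brain for 110 of 115. Without the axis position the evidence against chance is mixed. Of 100 splits of the 30 lesion libraries, the real one included, 4 gave as many calls. The highest other gave 3335, which points to a structure of the samples that can outweigh diet. With the real split included, 12 of 100 gave as many as the 2121 genes at an unadjusted p under 0.05 (highest other 7023). The calls fell to 6 without standard-diet library 70. With the axis position as covariate the real split gave 1715 and the highest of the other 59 splits 0. This 1 of 60 is the smallest share that 60 splits can give, and it argues against chance for that fit. The fit was chosen after seeing the data, among fits whose counts ran from 21 to 2324. The shared sign was reached by 1 of 100 splits of the intact libraries, the real one, with 109 of 115 as the highest other in either direction. After thinning to equal totals, the 113 of the 117 genes still tested had a median change of 99.5% of its value, and 68 genes were called. Thinning leaves each gene's expected share of counts as it was. It therefore argues only against a change made by low counts themselves, and cannot decide on a cause that goes with depth. No shift of one diet's lesions towards intact brain was detected, with mean positions of 1.01 on the ketogenic and 0.99 on the standard diet (permutation p = 0.922). As these means hardly differed, the position as covariate had little to take away. That 117 of 117 calls held with it is therefore not a separate test of such a shift. A sequencing or animal cohort cannot be told apart from diet, because 0 standard-diet libraries are numbered within the range of the ketogenic ones, so an effect of the diet on both tissues remains a hypothesis beside it.

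The second pattern is the spread of lesion libraries between intact brain and the far end of the axis. After thinning, the SD of the ketogenic positions was 0.356, against 0.350 before, which argues against counting noise from low totals as its source. Position went with total counts in that group (r = -0.638, permutation p = 0.00307, adjusted p = 0.0046 over 3 relations). By rank it did not pass after adjustment (rho = -0.533, permutation p = 0.0202, adjusted p = 0.0524), and r was -0.487 without the 2 farthest libraries. After thinning r stayed at -0.639. Thinning leaves each gene's expected share of counts as it was, so a cause that goes with depth was not decided. The relation with total counts was not seen on the standard diet (r = -0.0602, rho = -0.0455, permutation p = 0.854 and 0.904). A varying share of intact tissue in the samples may contribute, but the correlation of 0.981 between the readings from higher and lower genes does not favour it. Both gene sets were picked in these libraries, so any single factor along the axis gives a high r. As the whole cause, with a lesion profile common to all libraries, a varying share is argued against. That needs equal readings on the CPM scale, and their slope was 0.404 (0.515 with library totals only). A candidate explanation that stays open and untested is that lesions differ in how far the response has gone, in rising and falling genes alike on the log2 scale, where the slope was 0.962.

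The third pattern is the excess of unadjusted diet differences in intact brain, 2181 genes where 737 are expected. As many came from 3 of 100 splits, the real one included. After thinning 2029 genes were at an unadjusted p under 0.05, 1753 of them among the 2112 of the 2181 still tested. The median change of these 2112 in their direction was 0.29 on the log2 scale before and after. This argues against low counts themselves as the source. Thinning leaves each gene's expected share of counts as it was, so it cannot decide on a cause that goes with depth. Whether the share of the 20 most abundant genes accounts for a part was not decided. Within diet groups, the slope on this share times the diets' difference in share was taken. It had the sign of the diet difference for 81.8% of the 2181 genes and 63.1% of all genes tested. Its median size for the 2181 was 0.08 in that direction. The diet difference of the same libraries is roughly this product plus the difference left with the share as covariate. Genes picked for a large diet difference therefore share its sign more often by construction. The fall of their median change with the covariate restates the same quantity. With the share as covariate 704 genes were at the threshold, 457 of them among the 2181, but the loss is partly one of precision: the median change of the 2181 went from 0.29 to 0.21 and their median SE from 0.11 to 0.13, as the share differs between the diets. What sets this share was not tested, and an effect of diet on it stays open; with the share as covariate, 105 of the 115 lesion genes still had their lesion sign in intact brain.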

How the results depend on the processing

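Scaling by totals, thinning, the log2 scale for the lesion readings and the covariates of position and abundant genes were chosen after seeing the data. The total MCAO counts stayed within 1.5 times under every alternative run, but with library totals only their members and directions moved. On the standard diet 7781 of the 10563 calls were kept and 875 reversed, with 8162 rises and 2490 falls. On the ketogenic diet 8946 of the 10968 calls were kept and 327 reversed, with 7504 rises and 3357 falls. Leaving out single libraries gave 10273 to 10863 calls on the standard and 10629 to 11267 on the ketogenic diet. In intact brain, diet calls were 275 with DESeq2, 52 with 2 surrogate variables and 63 in the fit over all libraries, 0 under the other alternatives, and 0 to 170 without single libraries; the cause was not tested. In lesions, against 117, they were 466 with DESeq2, 933 with limma voom, 2324 with 2 surrogate variables, 1715 with axis position, 183 with library totals, 77 in the fit over all libraries, 68 after thinning and 21 without a low-count filter, which tests more genes; for the others, the cause was not tested. Leaving out single lesion libraries gave 6 to 242: without standard-diet libraries 70, 71, 82, 61, 66, 78, 64, 65 and 62 the counts were 6, 21, 23, 24, 36, 45, 57, 62 and 71. Without ketogenic libraries 29, 13, 31, 19, 15, 21, 41 and 7 they were 30, 34, 39, 43, 46, 48, 61 and 63, and without 9, 23 and 37 they were 179, 184 and 242. The interaction gave 2 calls with DESeq2, 13 with limma voom and 10 with 2 surrogate variables, 0 under the other alternatives, and 0 to 1 without single libraries (1 without ketogenic intact library 49); the cause was not tested. Pearson's r of the MCAO effects was 0.974 over genes of at least 1 CPM and 0.971 with DESeq2, and that of the diet effects 0.274 and 0.280. The larger spread of ketogenic lesions than of their intact group did not pass over all genes (difference 0.176, exact permutation p = 0.0248, adjusted p = 0.0744); the cause was not tested. The slope of the lesion readings was 0.404 on the CPM and 0.962 on the log2 scale. For the named IDs no alternative reversed a sign. The 8 entries for MCAO kept their calls, but the fitted log2 rises of ENSRNOG00000029949, ENSRNOG00000019043, ENSRNOG00000030187 and ENSRNOG00000010507 fell from 8.33, 8.31, 11.25 and 9.84 to 5.88, 6.77, 5.48 and 4.17 with limma voom; the cause was not tested; the 4 lesion diet IDs lost theirs in 15 of 44 refits, and the interaction IDs passed in 5 of 30. Not run, for want of gene names, were those of the gene lists and the covariate for tissue composition. No paired analysis was possible because no sample numbers are shared between groups. Depth limits what can be said of IDs with 3 or fewer counts in a group, for which folds are bounds or count ratios.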

Other observations

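The splits, the slopes on axis position and the library peaks below were examined after the data were seen. Over lesion libraries, with diet as a covariate, the genes that MCAO moves also moved along the axis position. Of 4785 genes higher in lesions on both diets, 3795 rose with position and 210 fell. Of 4552 genes lower on both diets tested within lesions, 3291 fell and 347 rose. Among these genes, with no minimum mean CPM set, 2245 higher and 637 lower genes changed at least 2-fold on both diets. Of them 7 higher and 8 lower genes moved against their direction. The axis was built from the same libraries, so this describes them and is not a separate test.

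With the position as covariate, the 1715 genes called for diet in lesions had a median size of 0.23 on the log2 scale, and 1698 of them were tested in intact brain, where 1476 (86.9%) had the same sign. Of 100 splits of the intact libraries 3, the real one included, reached this number in either direction, with 1524 as the highest other. As many as the 765 calls of the fit over both tissues came from 1 of 60 splits with diet redrawn within tissues, with 6 as the highest other. At an unadjusted p under 0.05, however, as many as the 3037 genes of this fit came from 3 of 60 splits, the real one included. The highest other was 3876, so the evidence against chance is mixed there. For the fit with position, 1 of 60, the real one, had as many as its 4259 (highest other 2620).

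Chance is argued against for the MCAO effect, as on each diet only the real split, 1 of 100, gave as many calls. That is the smallest share that 100 splits can give. The splits cannot tell MCAO from a batch that follows the sample numbers, which separate lesion from intact samples within each diet. On the standard diet the real count was 10563 and the highest other 6638, and on the ketogenic diet 10968 and 4681. Such large counts from other splits point to a structure of the samples, since a random split can hold more lesions on one side. For diet in intact brain and for the interaction, the real count was 0, so that all splits (100 of 100 and 60 of 60) have at least as many and the count says nothing about chance; the highest other counts were 473 and 20. At an unadjusted p under 0.05, as many as the 2181 genes of the diet in intact brain came from 3 of 100 splits (highest other 3054). As many as the 719 of the interaction came from 20 of 60 (highest other 2773). Both counts include the real split.

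Standard-diet intact library 83 held 35 genes at 5 CPM or more and over 5 times the next library of its group. Their median was 13.6 CPM, the largest 86.5 CPM, and together they made up 0.0547% of its counts; 23 of them were under 1 CPM in each of the 45 other libraries. In the fits, 5 of the 35 were tested for MCAO on the standard diet and 3 were called. Without library 83 the MCAO fit on the standard diet called 10534 genes.

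With 11 of the 19 ketogenic lesion libraries drawn at random 20 times, the MCAO count had a median of 10057, from 8990 to 11200, against 10563 on the standard diet with 11 lesion libraries.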
